A study of Mus musculus with 4 samples.

How the data were processed

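Single-cell gene expression was measured in 4 samples of mouse liver tumour tissue, 2 from Miz1F/F and 2 from Miz1Δhep mice. Per the labels' protocols, livers were digested, cells were loaded on a 10x Genomics Chromium controller, libraries were made with the Single Cell 3' v2 kit and sequenced on a HiSeq XTEN. Per the submitters' processing notes, CASAVA 1.8, Cell Ranger and Seurat were used with the mm10 mouse genome; the versions of Cell Ranger and Seurat, and the filters on cells and genes, are not given in the sources used here. The values deposited by the authors are the natural log of 1 plus the UMIs of a gene divided by the UMIs of its cell and multiplied by 10000. This was read from the values: turned back with the exponential, they sum to 10000 in every cell, and 100% of values above 0 are whole multiples of the smallest value of their cell within a tolerance of 0.001. Whole UMIs per gene and cell, and UMI totals over the listed genes, were computed from these multiples. The fewest genes in a cell were 201, so a limit of 200 genes per cell removed no cell.

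The table pools 4 barcode suffixes, and nothing in the sources used here maps cells to samples. The planned tests between genotypes (limma on class means, shares and gene lists) therefore could not be run as designed, and the genotype question stays open. In their place, values are given per barcode set or over all sets, and classes of cells were compared within each set; these comparisons were chosen after the table had shown that no genotype comparison was possible. Barcode sets are given as values, ranges and medians, and no p-values were computed. The gene lists, the cell type markers, the filter, the pseudocount and the alternatives listed with the plan were fixed before the data were examined. Depth ranged from 9093921 to 35033778 UMIs per set and the share of cells under 500 genes from 13.4% to 49.4%, so a level of 1 CPM in a small class rests on few molecules. Exact (Clopper-Pearson) intervals for shares and Poisson intervals for UMIs cover counting error only, and a count of 0 is given as the limit of 3 UMIs.

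Cells were clustered with scanpy 1.11.5 (anndata 0.12.19, python-igraph 0.11.9, scikit-learn 1.9.0) on 2000 highly variable genes, 30 principal components and 15 nearest neighbours, with Leiden clustering at resolution 1.0 and seed 1, which gave 28 clusters and no batch integration. Clusters were named from 17 marker lists by the mean log2 fold of the markers and their place among the leading 10 genes, into 15 named classes. Clusters with high markers of a second list, or with no marker among the leading genes, stayed unnamed. A cluster that scored highest for cholangiocyte markers did not have higher Krt19, Krt7 and Epcam, and by a rule set after the data were seen it was named only as the Krt8/Sox9 epithelial cluster. Erythroid cell-like cells were mixed: 122 of the 378 joined endothelial cell-like cells at resolution 0.5 and 124 joined the Krt8/Sox9 epithelial cluster at resolution 2.0. Scrublet, as run in scanpy per barcode set, called 6, 2, 0 and 1 cells as doublets in sets 1 to 4. Whether it missed doublets or few were left in the table was not tested. No cell was removed for the main values.

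The level of a gene in a class and set is the mean over cells of its share of the cell's UMIs, scaled to 1000000 UMIs (CPM); for Zbtb17 and Mtdh, given with Poisson intervals, it is the sum of UMIs over the class divided by all UMIs of the class. For a pair of classes, the log2 ratio of the levels plus 10 CPM was taken in each set with at least 20 cells of both classes, for genes with a mean of at least 20 CPM, and the median over sets is given with the lowest and highest set. A list value is the median over list members in each set, then over sets; markers of the compared classes were left out of lists. Each list median was placed among 10000 random lists of the same size matched on mean expression, as a description of these cells. Genes named in the text are Zbtb17 and Mtdh and, for each list given, up to 4 members of the highest mean level; other genes are said to be singled out after their values were seen, and genes of the class survey were chosen from the lists after seeing their levels. The sinusoidal endothelial, hepatocyte product and ribosomal protein lists of the first comparison, the heat shock, pericentral, cholesterol synthesis, lipogenesis and bile acid lists of the next, and the regulatory T cell list of the last, were added after their values were seen and are given as medians, without the rule for genes. The plan's further rules for named genes need a genotype test and were not used. Leading genes of a compared cluster were left out as single results in the text, and the values of 2 further genes that the rule names are not reported here. Gene positions and 17557 of the 17813 symbols (98.6%) were matched to GENCODE vM21 on GRCm38, the assembly that mm10 denotes. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

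The class comparison was tested on simulated UMIs with known changes. Sums of UMIs per class and set were drawn from a Poisson distribution with the same base profile in all sets. Levels came from these sums and not from means over cells, so the values below cover counting error only. Variation between cells and sets and free RNA were not simulated. For Kupffer cell-like against monocyte/macrophage-like cells (4551 genes), 86.3% of genes changed 2-fold and 100% of genes changed 4-fold had the right direction in every set, and 18.0% of unchanged genes went the same way in every set, where chance gives 12.5%. For the Krt8/Sox9 epithelial cluster against hepatocyte-like cells (4493 genes) these values were 96.7%, 100% and 26.5%, with chance at 25.0%. For T cell-like against NK cell/ILC1-like cells (4920 genes) they were 95.5%, 98.8% and 13.4%, with chance at 12.5%. Pseudocounts drew the recovered log2 ratios toward 0: true values of 1 and 2 came out at 0.83 and 1.78 in the first comparison, 0.89 and 1.72 in the next and 0.89 and 1.68 in the last. Alternatives were a pseudocount of 1, no filter or a filter of 100 CPM, weighting cells by UMIs, at least 500 genes per cell, Leiden resolutions of 0.5 and 2.0, removal of Scrublet calls, shares of non-hepatocyte cells and leaving out each barcode set. After the data were seen, clustering without the list genes (1788 variable genes), removal of cells with a Scrublet score above 0.25 and a scaling that sets the median ratio of all genes to 0 were added.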

Results

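Single-cell RNA libraries were prepared from digested liver tumour tissue of 5-month-old C57BL/6 mice. Tumours had been induced with the carcinogen diethylnitrosamine (DEN, 25 mg/kg at week 2 of age) and then weekly carbon tetrachloride (CCl4, 0.5 ml/kg). The samples formed 2 groups of 2, from mice with floxed Miz1 alleles (Miz1F/F) and from Miz1Δhep mice. The table held 24802 cells and 17813 genes, with 65920312 UMIs (unique molecular identifiers, which count RNA molecules) in all. Levels are given in CPM, the UMIs of a gene in 1000000 UMIs of its cells. Cell barcodes carried 4 suffixes, called barcode sets 1 to 4 here, and nothing in the sources used here pairs a suffix with a sample or a genotype. No value below compares the genotypes, and the barcode sets are not treated as replicates of a group. Set 1 held 2574 cells with 10718992 UMIs, set 2 held 6224 cells with 11073621 UMIs, set 3 held 4825 cells with 9093921 UMIs and set 4 held 11179 cells with 35033778 UMIs. The median UMIs per cell were 2648, 906, 1037 and 1859 in sets 1 to 4, and the median genes per cell were 920.5, 506, 568 and 823.

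Lymphoid and myeloid cells made up most of the tumour tissue suspension. B cell-like cells were the most frequent class, at 27.2% of all cells (95% exact interval 26.7% to 27.8%), ahead of endothelial cell-like cells at 11.5%, T cell-like cells at 9.73% and monocyte/macrophage-like cells at 9.56%. Kupffer cell-like cells, the resident macrophages of the liver, made up 8.09%, neutrophil-like cells 5.59%, dendritic cell-like cells 4.69%, NK cell/ILC1-like cells 3.996% and plasmacytoid dendritic cell-like cells 3.90%. Hepatocyte-like cells made up 4.78%. A separate epithelial cluster with Krt8, Sox9 and Hnf4a but little Krt19 held 3.12% of cells and is called the Krt8/Sox9 epithelial cluster. Plasma cell-like cells made up 3.04%, erythroid cell-like cells 1.52%, basophil/mast cell-like cells 0.560% and cholangiocyte-like cells 0.395%, and 2.29% of cells stayed unnamed. Shares differed widely between barcode sets. Kupffer cell-like cells ranged from 1.47% to 12.5%, neutrophil-like cells from 2.72% to 17.4% and hepatocyte-like cells from 1.16% to 9.29%. At Leiden resolution 2.0, 94 hepatocyte-like cells became unnamed. An unnamed cluster at that resolution held 94 cells, 89 of them in set 1, with high hepatocyte and erythroid markers. The 9.29% of hepatocyte-like cells, found in set 1, may therefore depend on the clustering. B cell-like cells ranged from 17.1% to 30.5%, and different clusters held most of them in different sets. A digest loses fragile cells, so these are shares of the recovered cells and not of the tissue.

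**Figure D1:**
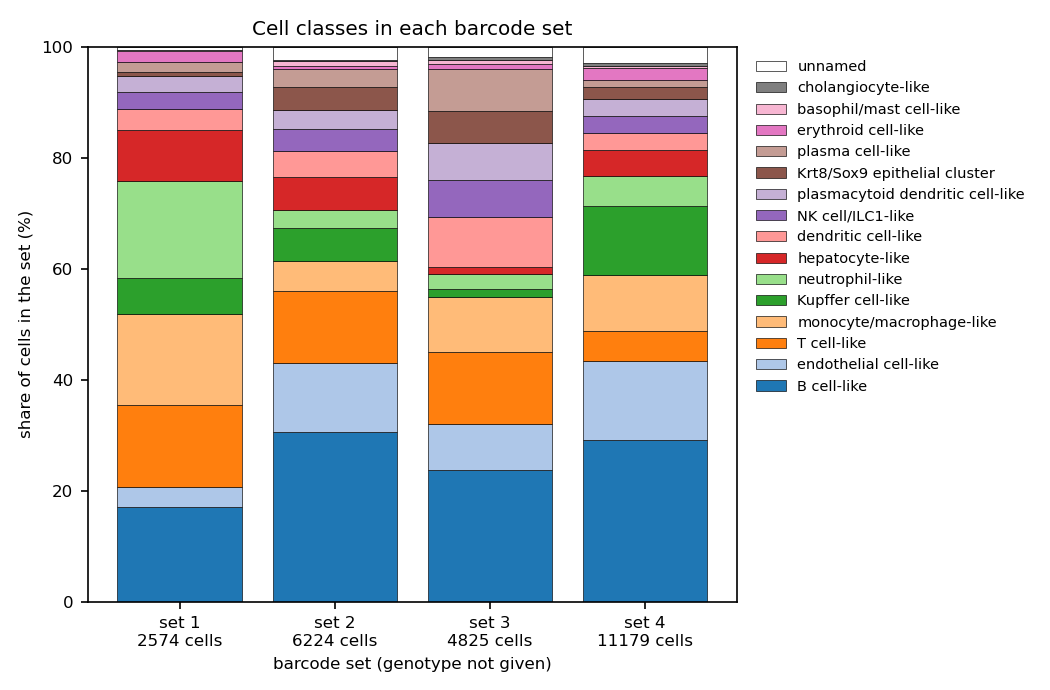
Stacked bars give the share of cells (%) in each named class for each of the 4 barcode sets, whose genotype is not given in the sources used here. B cell-like cells took 17.1% to 30.5% of each set, and neutrophil-like cells reached 17.4% in set 1.

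Few UMIs of Zbtb17, the gene that encodes Miz1, were counted in 13 of the 15 named classes, hepatocyte-like cells included, with no correction for free RNA in the droplets. In GENCODE vM21 on GRCm38 it lies on the plus strand of chromosome 4 from 141444654 to 141467930. Hepatocyte-like cells held 35 Zbtb17 UMIs among 5233888, or 6.69 CPM (95% Poisson interval 4.66 to 9.30), with 7, 13, 3 and 12 UMIs in sets 1 to 4. The Krt8/Sox9 epithelial cluster held 75 UMIs, or 12.5 CPM (9.80 to 15.6), with 6, 12, 25 and 32 UMIs in sets 1 to 4. This pooled difference from hepatocyte-like cells was not seen in every set. The cluster stood at 6.96 CPM against 6.21 in set 2 and at 16.1 against 17.3 in set 3. In set 4 it stood at 12.8 against 5.15, and in set 1 it was also higher, from 19 cells. Erythroid cell-like and basophil/mast cell-like cells held 0 Zbtb17 UMIs, which allows up to 2.49 and 15.2 CPM. Mtdh encodes the NF-kB cofactor metadherin (chromosome 15, 34082694 to 34145624, plus strand). With all sets pooled, it was above its hepatocyte-like level in every named class except erythroid cell-like cells. Erythroid cell-like cells were higher in sets 2 and 3, at 153.9 against 73.6 and 73.0 against 51.9 CPM, from 10 and 9 UMIs. T cell-like cells in set 2 stood close, at 81.5 against 73.6 CPM, and the Kupffer cell-like value of set 3 rested on 4 UMIs. Plasmacytoid dendritic cell-like cells had 370.4 CPM of Mtdh (346.5 to 395.5), plasma cell-like cells 307 (293 to 323) and B cell-like cells 202 (192 to 212). Mtdh stood at 77.6 CPM (70.2 to 85.5) in hepatocyte-like cells and at 150.02 (140.4 to 160.1) in the Krt8/Sox9 epithelial cluster. A 3' tag can lie outside the deleted part of Zbtb17 and so does not check the deletion, and the Zbtb17 counts were not used to assign a genotype to any set.

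Several inflammatory genes were highest in neutrophil-like cells and low in hepatocyte-like cells. The NF-kB inhibitor gene Nfkbia had a median over the sets of 3470 CPM (sets 2547 to 4751) in neutrophil-like cells, 2421 in Kupffer cell-like cells and 2195 in monocyte/macrophage-like cells, against 147 in hepatocyte-like cells and 391 in the Krt8/Sox9 epithelial cluster. Il1b reached 4505 CPM and the neutrophil chemokine gene Cxcl2 5782 CPM in neutrophil-like cells, and Cxcl2 was highest there in all 4 sets. Cxcl1, another neutrophil chemokine gene, was highest in the Krt8/Sox9 epithelial cluster, at 1002 CPM (sets 956 to 1343), with 211 in Kupffer cell-like cells. Ccl24 stood at 430.4 CPM in Kupffer cell-like cells (sets 265 to 512) and was highest there in all 4 sets. Relb and Traf1 were highest in dendritic cell-like cells in all 4 sets, at 131 and 246 CPM. Of the 26 NF-kB targets and regulators with at least 20 CPM in a class, 6 were highest in neutrophil-like, 5 in monocyte/macrophage-like, 5 in basophil/mast cell-like and 4 in dendritic cell-like cells. This ranking is by medians over sets, and in the same order only 2, 0, 0 and 2 of them were highest there in every set. Basophil/mast cell-like cells numbered 139, with 5 in set 1, where the class had no value. This class therefore could not be highest in every set, and its 0 says nothing about differences between sets. Cdkn1a, a p53 target that Miz1 and Myc also regulate, was highest in the Krt8/Sox9 epithelial cluster at 1963 CPM, as was Myc at 108.

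**Figure D2:**
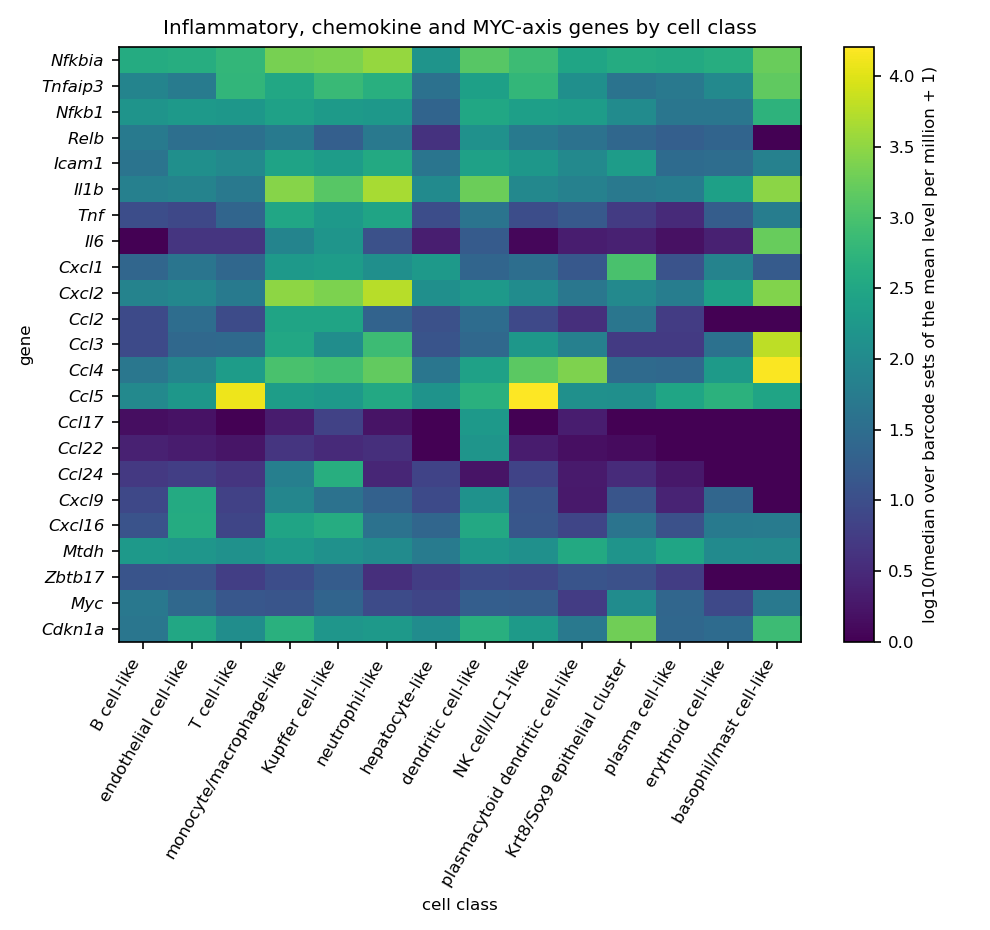
The heat map shows the mean level of each gene in each class as log10 of the median over barcode sets of the level in CPM plus 1, for classes with at least 20 cells in 3 or more sets. Nfkbia, Il1b and Cxcl2 were brightest in neutrophil-like cells (3470, 4505 and 5782 CPM), and Cxcl1 in the Krt8/Sox9 epithelial cluster (1002 CPM).

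Kupffer cell-like and monocyte/macrophage-like cells, the resident and the mostly recruited macrophages of the liver, differed in several inflammatory genes within each barcode set. Il1b was lower in Kupffer cell-like cells in every set, with a median log2 ratio of -1.11 (sets -1.53 to -0.72) and 1283 against 2760 CPM. The mannose receptor gene Mrc1 was higher in every set, at 2.63 (2.39 to 3.12) with 556 against 80.0 CPM, although endothelial cell-like cells had more of it (1014 CPM), and so was Ccl24, at 2.88 (0.66 to 4.37). Tgfb1 was lower in every set, at -0.77 (-0.84 to -0.38), and the lysosomal protease gene Ctsb was higher, at 1.61 (1.15 to 1.90). The immediate early gene Egr1 was higher at 1.84 (1.68 to 2.74) and the interferon-induced gene Ifitm3 lower at -1.14 (-1.29 to -0.95). Nfkbia went both ways, from -1.04 to 0.94. Among NF-kB genes singled out after their values were seen, Traf1 was lower at -3.08 and Tnfaip3 higher at 1.08 in every set.

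As a list, the 26 NF-kB genes had a median log2 ratio of -0.51 (sets -1.04 to -0.22), below all but 0.02% of 10000 random lists matched on expression. Of these genes 12 were lower and 2 were higher in every set, and the median was -0.20 for genes with at least 100 CPM. The 7 MHC class II genes lay at -1.46, below all random lists, but at 0.21 in set 1, the only set in which H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were higher in Kupffer cell-like cells. The 12 alternatively activated macrophage genes lay at 0.53, above 98.0% of random lists, with 0.30 when set 1 was left out and 1.05 when set 2 was. The size of this value also depended on the filter on low values, as given below. Sinusoidal endothelial genes, which share Mrc1 and Stab1 with that list, lay at 1.11 (9 genes, percentile 100), and abundant hepatocyte products at 0.91 (15 genes, percentile 99.97), so RNA of other cells is not excluded, although Fcna and Apoe of these lists were also high in Kupffer cell-like cells (2126 and 10311 CPM). Ribosomal protein genes lay at -0.62 (26 genes, 24 lower in every set), and Kupffer cell-like cells were shallower, with medians of 1933, 859, 691 and 1587 UMIs per cell against 6234, 1615, 1511 and 3413.5 in sets 1 to 4. The 17 immediate early genes lay at 0.46, above 98.2% of random lists, and the 21 interferon response genes at 0.24, above 72.1%. Pro-inflammatory macrophage genes (18 genes, 0.07, sets -0.94 to 0.09), chemokines (14 genes, 0.10, sets -0.65 to 0.14) and lipid-associated macrophage genes (13 genes, 0.03, sets -0.29 to 0.31) had members that went both ways and moved to -0.10, -0.07 and -0.13 when the median of all genes was set to 0. Trem2 and Gpnmb of the lipid-associated list were left out as monocyte/macrophage markers. Both were among the leading genes of a monocyte/macrophage-like cluster, so the list value does not cover them. With the filter applied anew, leaving out set 3 also turned the pro-inflammatory genes to -0.02 and the lipid-associated genes to -0.11. Leaving out set 4 turned the latter to -0.11. The median of all genes was 0.16 over 5331 genes. With this median set to 0 in each set the NF-kB list lay at -0.68 and MHC class II at -1.63. Alternatively activated genes then lay at 0.34, immediate early genes at 0.29 and interferon response genes at 0.07. Of all genes, 182 were at least 2-fold higher and 132 at least 2-fold lower in every set, and 45.7% went the same way in every set, where chance gives 12.5%.

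As lists, p53 target and immediate early genes were higher in the Krt8/Sox9 epithelial cluster than in hepatocyte-like cells, and periportal and xenobiotic metabolism genes were lower. Cdkn1a was higher in each of sets 2 to 4, with a median log2 ratio of 3.88 (3.57 to 3.92) and 1963 against 124 CPM. The stress cytokine gene Gdf15 was higher at 3.30 (2.98 to 3.54), with 658 against 74.7 CPM, the antiproliferative gene Btg2 at 2.36 (2.34 to 2.92) and the apoptosis gene Bax at 1.87 (1.72 to 3.27). Fos was higher at 3.14 (2.91 to 3.30), with 3382 against 335 CPM. Cxcl1 was higher at 2.82 (2.28 to 3.61), Ier3 at 3.79 (3.35 to 3.86) and Nfkbia at 1.47 (0.70 to 2.32). The fetal liver gene Afp was lower at -1.67 (-1.83 to -1.06), with 199.5 against 734 CPM, and Tff3 at -4.70 (-5.94 to -4.10). Of the 10 fetal and liver tumour markers 5 were lower but 4 were higher in every set. This list kept Spp1 and the acute phase list kept Cp. Both are leading genes of the cluster, so their levels there are no independent result. The urea cycle gene Ass1 was lower at -1.78 (-2.61 to -1.58). Hsd17b13, the periportal gene of the highest mean level, was higher in every set at 0.57, but came to -0.0049 with cells weighted by UMIs. Of the 10 periportal genes 7 were lower and 1 was higher in every set. Mdm2, singled out after its values were seen, was higher at 3.24.

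All 14 p53 targets were higher in the Krt8/Sox9 epithelial cluster in sets 2, 3 and 4, and 12 of them by at least 2-fold. The list median was 2.45 (2.32 to 2.53), above 100% of 10000 matched random lists. The 17 immediate early genes lay at 2.60 (2.36 to 2.67), also above 100%, with 16 higher in every set. They share Btg2 with the p53 targets and Ier3 with the NF-kB genes, so these lists are not separate results. The 20 NF-kB genes lay at 0.82 (0.54 to 1.76), above 99.4%, at 1.29 without set 4, at 1.801 for genes with at least 100 CPM and at 1.52 at Leiden resolution 2.0. Heat shock genes, which handling of cells can raise, lay at 1.07 (12 genes, sets 0.84 to 1.45, percentile 99.73), with 10 higher in every set. Periportal hepatocyte genes lay at -1.82 (10 genes) and xenobiotic metabolism genes at -1.55 (12 genes), both below all random lists, and at -1.57 and -1.20 when cells were clustered without the list genes. Other hepatocyte genes were lower too: pericentral genes lay at -1.35 (9 genes, -0.40 without set 3 and -2.06 without set 4), cholesterol synthesis genes at -1.08 (16 genes), lipogenesis genes at -0.98 (10 genes) and bile acid genes at -0.60 (7 genes, -0.997 without set 3 and -1.47 without set 4). Values without a set can also reflect list members that changed when the filter was applied anew. Several of these sizes, and that of fatty acid oxidation genes, moved further under other settings, as given below, with their signs kept. Fatty acid oxidation genes lay at -0.31 (12 genes, percentile 3.74) and acute phase genes at -0.13 (13 genes, percentile 7.95; -0.37 without set 3, -0.31 without set 4 and -0.74 with at least 500 genes per cell). Fetal and liver tumour markers lay at -0.37 (10 genes, percentile 5.56; -0.63 without set 2 and -0.65 without set 3), with 4 higher and 5 lower in every set, and at 0.00 with no filter on low values. The median of all 5286 genes was 0.35; with it set to 0 in each set p53 targets lay at 1.97, immediate early genes at 2.12, NF-kB genes at 0.47, acute phase genes at -0.55, fetal and tumour markers at -0.83 and fatty acid oxidation genes at -0.64. Of all genes, 414 were at least 2-fold higher and 227 at least 2-fold lower in every set, and 62.6% went the same way, where chance gives 25.0%. Set 1 held 19 cells of the cluster and was not used, and the cluster was deeper than hepatocyte-like cells, with medians of 5394, 4658 and 10746 UMIs per cell against 3018, 729 and 1781 in sets 2 to 4.

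**Figure D3:**
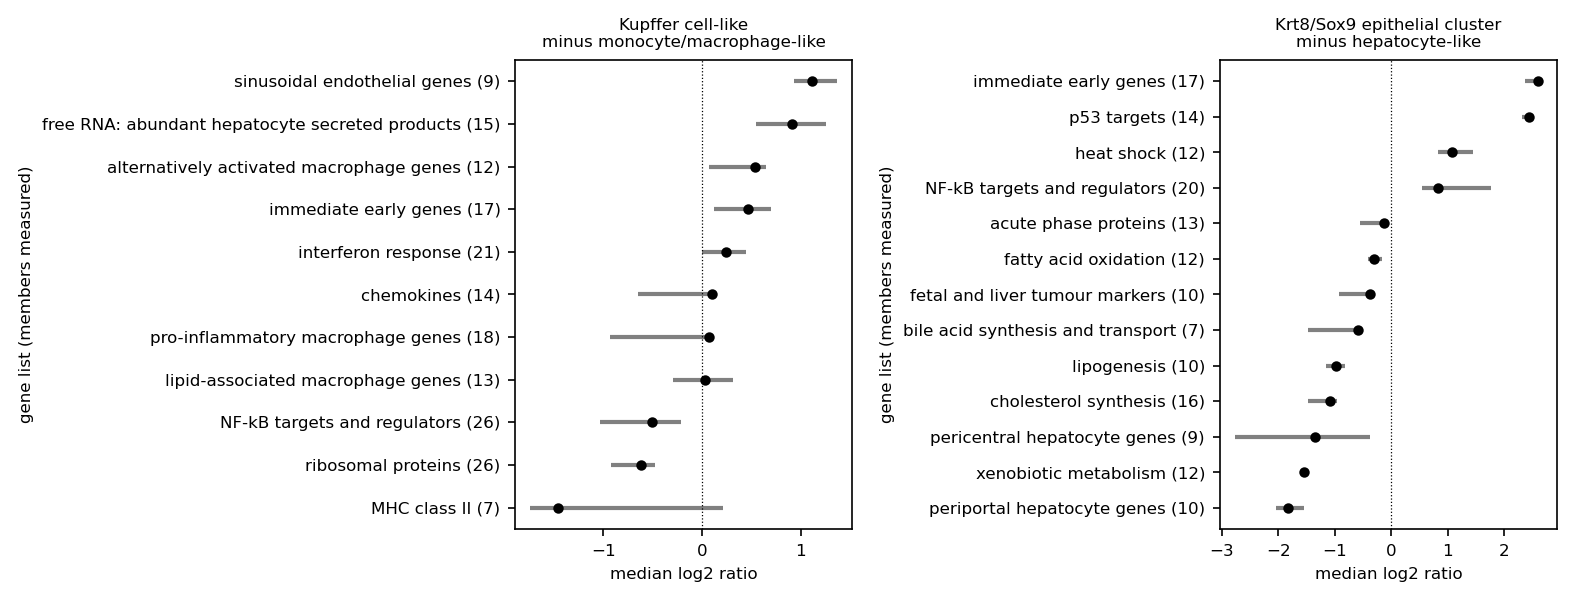
Points give the median log2 ratio of each gene list between the named classes as a median over barcode sets, and bars run from the lowest to the highest set; the number of genes is in brackets. In the comparison of the Krt8/Sox9 epithelial cluster with hepatocyte-like cells, p53 targets (2.45) and immediate early genes (2.60) lay farthest above 0 and periportal genes (-1.82) farthest below it.

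As lists, cytotoxic effector genes were lower and naive lymphocyte genes higher in T cell-like than in NK cell/ILC1-like cells, with some members that went the other way. The granzyme gene Gzmb was lower in T cell-like cells in every set, at -1.21 (sets -2.19 to -0.87), as were Nkg7 at -0.75 (-1.51 to -0.64) and Klrd1 at -1.73 (-1.94 to -1.57). The inhibitory receptor gene Ctla4 was higher at 1.99 (1.35 to 2.87) and Cxcr6 at 1.14 (0.28 to 1.54), while Cd160 was lower at -1.40 (-1.97 to -1.05). The homing receptor gene Ccr7 was higher at 2.36 (1.98 to 2.85). Nfkbia was lower in every set, at -0.46 (-0.94 to -0.25).

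Cytotoxic effector genes had a median log2 ratio of -0.71 (12 genes, sets -1.08 to -0.38) and NF-kB genes of -0.38 (23 genes, -0.97 to -0.27), below all and all but 0.10% of random lists. Exhaustion genes lay at 1.09 (8 genes, -0.03 to 1.46) and naive lymphocyte genes at 1.37 (9 genes, 0.55 to 1.90), both above 100% of random lists. Of the exhaustion genes 4 were higher and 1 was lower in every set. Because Pdcd1, Tox, Lef1 and Tcf7 led T cell-like clusters, these lists were also taken from cells clustered without the list genes, where exhaustion genes lay at 0.96 and naive genes at 0.90. With at least 500 genes per cell they lay at 0.30 and 0.80, and naive genes at 0.25 for genes with at least 100 CPM. Over 4948 genes the median was -0.10, and 32.7% of genes went the same way in every set, where chance gives 12.5%. T cell-like cells pooled several clusters, so these are differences between pooled classes. Regulatory T cell genes, which share Ctla4 with the exhaustion list, also lay higher, at 1.03 (6 genes, sets 0.47 to 1.25).

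Transcripts of hepatocytes and red cells were found in every class. Alb stood at 44005 CPM in hepatocyte-like cells, and in B cell-like cells it was at 349, 4096, 386 and 2399.8 CPM in sets 1 to 4. T cell-like cells held 264, 3265, 266 and 1800.2 CPM of Alb in the same sets. Hbb-bs stood at 235792 CPM in erythroid cell-like cells and between 634 and 2529.8 CPM, as medians over sets, in the other classes. These levels bound the free RNA in the droplets, so low levels of hepatocyte genes in immune classes were not read as expression. The table listed 0 mitochondrially encoded genes, so the mitochondrial share of cells was not analysed here.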

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

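Clustering without the list genes, the Scrublet score limit and the scaling to a median ratio of 0 were chosen after the data were seen, as were the class comparisons themselves and, among the lists, those of sinusoidal endothelial, hepatocyte product, ribosomal protein, heat shock, pericentral, cholesterol synthesis, lipogenesis, bile acid and regulatory T cell genes. The regulatory T cell list was given without alternatives and is not counted below. Leaving out a set also applied the filter anew, so list members could differ from those of the main value. Of 401 alternative values of the 28 list medians, 345 moved by less than the SD over barcode sets and 55 by more; the causes were not tested. In the pro-inflammatory, chemokine, lipid-associated, and fetal and tumour marker lists 13 values changed sign or came to 0; each other list kept its sign under every alternative run. No paired analysis was possible because nothing maps cells to samples, so the planned limma fits, count tests, replicate block and scaling of libraries were not run.

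For Kupffer cell-like minus monocyte/macrophage-like cells, alternatively activated genes (0.53) moved to 0.23 with no filter, 1.42 with a filter of 100 CPM and 0.85 with cells weighted by UMIs, and ranged from 0.30 to 1.05 when each set was left out. NF-kB genes (-0.51) came to -0.20 with the filter of 100 CPM, a move within the SD over sets. Sinusoidal endothelial genes (1.11) moved to 1.46 with a pseudocount of 1, 0.54 with no filter and 1.69 with at least 500 genes per cell.

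Most moves beyond the SD were in the Krt8/Sox9 epithelial cluster minus hepatocyte-like cells. With a pseudocount of 1, p53 targets moved to 2.93, periportal genes to -2.33, xenobiotic genes to -1.65 and lipogenesis genes to -1.18. With no filter, periportal genes moved to -1.53, xenobiotic genes to -1.27, lipogenesis genes to -0.59 and fetal and tumour markers to 0.00, which ends their direction. With a filter of 100 CPM, p53 targets moved to 2.90, NF-kB genes to 1.801, cholesterol synthesis genes to -1.70 and fetal and tumour markers to -1.10. With cells weighted by UMIs, p53 targets moved to 2.07, immediate early genes to 2.22, acute phase genes to -0.53, cholesterol synthesis genes to -1.58, bile acid genes to -1.67 and lipogenesis genes to -1.24. With at least 500 genes per cell the first 5 of these moved to 2.22, 2.28, -0.74, -1.52 and -1.81, and heat shock genes to 0.75. At Leiden resolution 2.0, p53 targets moved to 2.27, NF-kB genes to 1.52, xenobiotic genes to -1.46, fetal and tumour markers to -0.99, bile acid genes to -1.52 and fatty acid oxidation genes to -0.16. Clustered without the list genes, p53 targets moved to 2.56, immediate early genes to 2.78, periportal genes to -1.57, xenobiotic genes to -1.20 and bile acid genes to -1.27. With the median ratio of all genes set to 0, p53 targets moved to 1.97, immediate early genes to 2.12, periportal genes to -2.30, xenobiotic genes to -1.93, acute phase genes to -0.55, fetal and tumour markers to -0.83, cholesterol synthesis genes to -1.44, lipogenesis genes to -1.33 and fatty acid oxidation genes to -0.64. When each set was left out, lipogenesis genes ranged from -1.07 to -0.78 and bile acid genes from -1.47 to -0.56. Fatty acid oxidation, lipogenesis, bile acid, pericentral and sinusoidal endothelial genes and the exhaustion genes below had too few members for a value with the filter of 100 CPM.

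For T cell-like minus NK cell/ILC1-like cells, exhaustion genes moved to 0.30 and naive genes to 0.80 with at least 500 genes per cell, and naive genes to 0.25 with a filter of 100 CPM.

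Of 969 alternative values of 77 named genes, 923 stayed within the SD over sets and 44 moved; 25 values of 11 genes changed sign. Of genes with the same direction in every set, those that changed sign were Hp, from -0.15 to 0.0058 when clustered without the list genes, and Hsd17b13, from 0.57 to -0.0049 with cells weighted by UMIs. Of 300 values of Zbtb17 and Mtdh levels, 284 stayed within their Poisson intervals and 16 moved. Of 164 values of the 15 shares, 96 stayed within their exact intervals and 68 moved; with at least 500 genes per cell 14 moved, since that limit removes 49.4% of set 2 and 13.4% of set 4. Levels in sets 2 and 3 rest on medians of 906 and 1037 UMIs per cell.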

Other observations

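Chosen after the result was seen were the test of a mixture of subtypes for Malat1, the tests of a doublet, of free RNA and of digestion stress for the Krt8/Sox9 epithelial cluster, and the comparison of UMIs for the mixed cluster; the other tests below were written before their result. Genotype is a biological factor of the design, but it could not be tested for these patterns, since no barcode set is mapped to a sample. Apart from a cell type of its own for the mixed cluster and a mixture of subtypes for Malat1, no biological explanation was tested.

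A cluster of 438 cells carried both Kupffer and endothelial markers and was left unnamed. In sets 2, 3 and 4, which had at least 20 such cells, the shares that the markers kept of the level in each parent class summed to 0.982, 0.786 and 1.13 (median 0.982), near the 1 that 2 cells in one droplet would give. The lower of the shares had a median of 0.432, too high for free RNA. Only S100a8 and S100a9 of 3413 genes (0.0586%) lay more than 2-fold above both parent classes, which argues against a cell type with many genes of its own. A cell type with the genes of both parent classes at or below their levels would give the same result, so that case stays open. Doublet scores were higher in this cluster, with a median of 0.0880 against 0.0422 in all cells, but its median UMIs of 1438, 795 and 3648 were only 0.649, 0.476 and 0.715 times the summed medians of both parent classes. Whether these droplets held 2 cells therefore stays open.

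Malat1, a nuclear RNA, differed between barcode sets within each class, with a median over 12 classes of 3.21 for the highest set over the lowest. In B cell-like cells Malat1 stood at 39907, 11381, 17471 and 44359 CPM in sets 1 to 4. Among cells with 800 to 1600 UMIs the ratio was 4.47 as a median over 4 classes, so the UMI total of a cell alone did not account for it. That window takes unlike cells from each set, since T cell-like medians were 3270 UMIs in set 1 and 810 in set 2. In the window the highest set changed from 4 to 1 in B cell-like, T cell-like and monocyte/macrophage-like cells. A difference in depth between sets is therefore not excluded. Within 14 finer clusters (Leiden resolution 2.0) with cells of all sets the ratio was 3.05 as a median (1.99 to 6.17), which argues against a different mixture of the subtypes that such clusters separate. The ratio of set 4 to set 2 was correlated across genes between classes, with a median Pearson correlation of 0.622 over 66 pairs of classes (0.385 to 0.847), where genes are not independent replicates. A library or sequencing batch cannot be told apart from a difference between whole animals or genotypes, since no label ties a set to an animal, a genotype or a run.

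Cells of the Krt8/Sox9 epithelial cluster carried the hepatocyte transcription factor gene Hnf4a at 199, 133 and 137 CPM in sets 2, 3 and 4, against 199, 211 and 108 in hepatocyte-like cells. In sets 3 and 4 Sox9 kept 0.558 and 0.757 of its cholangiocyte-like level, but Krt19 kept 0.00323 and 0.00274 and Epcam 0.00997 and 0.00663. Krt19 and Epcam that were not raised were part of the rule that named the cluster, so their low shares are no test. The 18 duct genes chosen without this cluster kept a median of 0.130 times the share of Sox9 (0.166 and 0.0946). This argues against a hepatocyte and a cholangiocyte in one droplet. A first bound on the upper quartile of the 18 genes was not met in set 3 (0.551) and was dropped. At their lower quartile the 18 genes kept 0.0399 and 0.00674 of the cholangiocyte-like level in sets 3 and 4. A duct cell that brought the Sox9 would bring more of these genes. In the same sets 5 and 2 of the 18 genes kept at least 0.5 times the share of Sox9. The ratio of Hnf4a to Alb was 6.44 times that in hepatocyte-like cells (3.17 to 7.46), which argues against free RNA; this test replaced a comparison of Hnf4a with its highest level in non-epithelial classes (3.94-fold as a median), which decided nothing and in set 3 went the other way, with 178 CPM in erythroid cell-like cells, a mixed class, against 133. Stress during digestion stays open: among cells with at least 3000 UMIs, Krt8, Sox9 and Spp1 summed were 1.06 times as high at the lowest as at the highest Fos shares, which decides nothing, since these genes define the cluster; the ratio was 1.05 in set 2, where the lowest shares had 181 CPM of Fos against 255 in hepatocyte-like cells, and 1.18 and 1.06 in sets 3 and 4, where they still had 1490.4 and 1231 against 416 and 335.

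A cluster of 72 cells with cell cycle genes scored highest for endothelial markers, and a cluster of 59 cells, 46 of them in set 3, carried stellate and mesothelial markers. Both stayed unnamed.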
